A study of Mus musculus with 3 samples.

How the data were processed

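The series measured mRNA in B16 mouse melanoma cells at 0, 2 and 4 h of treatment with 1 µg/ml doxorubicin, with 1 array per time point. Per the labels' protocols, cells were grown in medium with serum, total RNA was extracted with Trizol, and biotinylated cRNA was made by the array maker's standard protocol. Per the file headers, the arrays were of the Mouse430_2 design. GCOS 1.4 is the 1 tool named in the submitters' processing notes, and the signal algorithm is not given in the sources used here. The deposited values are probe set intensities on a linear scale, already scaled by the authors, since the 2% trimmed mean over all 45101 probe sets is 150.0 on each array. Detection calls and probe-level files were not analysed here. Arrays were assigned to time points from their titles. The description field names bone marrow-derived macrophages, and it and the source field name an "ET" treatment that the labels do not expand, so marker genes of several cell types were set side by side and no array was regrouped.

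From the deposited intensities, each array was rescaled to a 2% trimmed mean of 500, signals under 100 were set to 100, and log2 was taken. A probe set passed if its mean log2 signal over the 3 arrays was at least that of a signal of 200. Of 45101 probe sets, 64 are controls. The annotation table for the platform lists 35890 probe sets, of which 34958 carry 1 gene symbol and 932 several, and 9211 are not listed and stay unnamed here. Symbols were updated by Entrez gene ID to the RefSeq table of assembly GRCm38.p6 for 34754 of the 34958 probe sets, and the others kept the table's symbol. Probe sets with 1 symbol stood for genes, and a gene took its passing probe set with the highest mean log2 signal. This left 15785 probe sets and 9723 genes, of which 3905 genes had at least 2 passing probe sets.

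With 1 array per time point no test, p-value or standard error was computed. Genes were counted by a fixed size of at least 2-fold (log2 ratio of 1). The probe-level error is the SD of log2 ratios between different probe sets of a gene, adjusted for the number per gene. It was 0.26 in the brightest of 4 bins of probe sets by signal and 0.54 in the dimmest bin for 2 h against 0 h, and 0.31 and 0.64 for 4 h against 0 h. It leaves out variation between cultures and arrays and includes real differences between transcripts of a gene. Unchanged arrays were simulated 100 times by drawing such deviations from probe sets of like signal, with a shared 0 h array, and this was repeated in 3 other scalings after the counts were seen. Where a gene had several passing probe sets, the SD over them is printed with its log2 ratio. A signal under the floor on 1 side gives a bound, written as "at least".

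Before the data were examined, 22 gene lists with 391 entries, the rule for naming genes and the alternatives were fixed. For 2 h and for 4 h against 0 h, the rule took the 12 highest and 12 lowest genes above the floor on both arrays whose passing probe sets all had the same sign and a size of at least 0.58. It also took up to 3 genes per direction with 1 array at the floor, the 2 highest and 2 lowest members of each list at 4 h, and the 3 brightest markers of each cell type. Names that matched fixed patterns of clone and predicted names were left out, and AY036118, a sequence accession, matched none of them. Other genes named in the text are said to be chosen after their values were seen. Each list's median log2 ratio, over members passing the filter, was placed among 10000 random lists of the same size drawn from 20 bins of mean expression. Percentiles up to 2.5 or from 97.5 were read as standing apart. Lists with under 3 passing members have no median. Gene length was the genomic span in GRCm38.p6, known for 9712 genes.

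The counting and list steps were tested on simulated data for 4 h against 0 h with 9811 genes. Of 50 genes planted at each size, a log2 ratio of -1 was found beyond 2-fold in 48.0%, and ratios of -2, -3 and 2 in 100% each. Among unchanged genes 148 were counted as lower and 156 as higher, against 130 and 131 estimated by the simulation of unchanged arrays. A list of 20 genes planted at -1 stood at percentile 0, and 3 of 100 unchanged lists stood apart. Alternatives were the values as deposited, scaling to equal medians of passing probe sets, quantile normalization, floors of 50 and 200, an offset of 50 in place of a floor, no filter, a filter of 400, the mean over a gene's probe sets, and leaving out probe sets with _x_at, _s_at or _a_at names. Scaling to the 18 hybridization spike-in probe sets was added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.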

Results

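Gene expression was measured in B16 cells, a mouse melanoma cell line, at 0, 2 and 4 h after addition of 1 µg/ml doxorubicin. Doxorubicin is an anthracycline that intercalates into DNA and poisons topoisomerase II. Total RNA from each time point was hybridised to 1 Affymetrix Mouse430_2 array, so the series held 3 arrays with no replicates. No difference between time points could therefore be set against a spread between cultures, and no test across cultures was made. The series held no untreated culture at 2 h or 4 h, so doxorubicin cannot be told apart from time in culture or handling. The number of arrays limits the precision of every ratio below. A probe-level error was taken instead from the spread of log2 ratios between different probe sets of the same gene. Its SD was 0.40 for 2 h against 0 h and 0.48 for 4 h against 0 h, and it leaves out variation between cultures and arrays. After scaling, the median signal over the 45101 probe sets was 154 at 0 h, 136 at 2 h and 126 at 4 h. The share of probe sets with a signal of at least 200 was 43.4%, 40.0% and 38.2%. In all, 9723 genes passed the expression filter.

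Cell type markers were read first, because the labels named both B16 melanoma cells and, in the description field, bone marrow-derived macrophages (BMDM). Pigment cell genes were among the brightest signals on every array. Tyrp1, a melanosomal enzyme, had a signal of 42568 at 0 h, 44083 at 2 h and 47128 at 4 h. Dct, an enzyme of melanin synthesis, had signals of 35050, 39355 and 42058, and Pmel, the structural protein of melanosome fibrils, 35665, 46371 and 45805. Of 17 pigment cell markers on the array, 16 had a signal of at least 200 at 0 h, 14 at 2 h and 15 at 4 h, and the median signal was 3976, 2200 and 1196. Macrophage markers had a median over 21 genes of 100.1 at 0 h, 63.0 at 2 h and 146 at 4 h, under the filter of 200 on each array. Probe sets differ in affinity, so signals of different genes are set side by side here and do not measure a share of cells. A signal of at least 200 was found for 7, 6 and 6 of them. Cd68, a lysosomal glycoprotein that other cell types also express, was the brightest macrophage marker, at 1884, 3044 and 3699. Csf1r, the receptor of macrophage colony-stimulating factor, had signals of 522, 424 and 376, and Lyz2, a lysozyme, 372, 414 and 398. Among 9 fibroblast markers, 3 reached 200 on each array, namely the collagens Col1a1 (1702, 2253 and 2109) and Col1a2 (731, 478 and 304) and the matrix protein Postn (766, 788 and 1091). Lymphocyte markers reached 200 in 2, 2 and 1 of 7 genes, led by Cd8a at 344, 537 and 463. Of 7 endothelial markers, 1 reached 200 on each array, the receptor Kdr at 298, 431 and 253. No array was regrouped from these values.

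**Figure D1:**
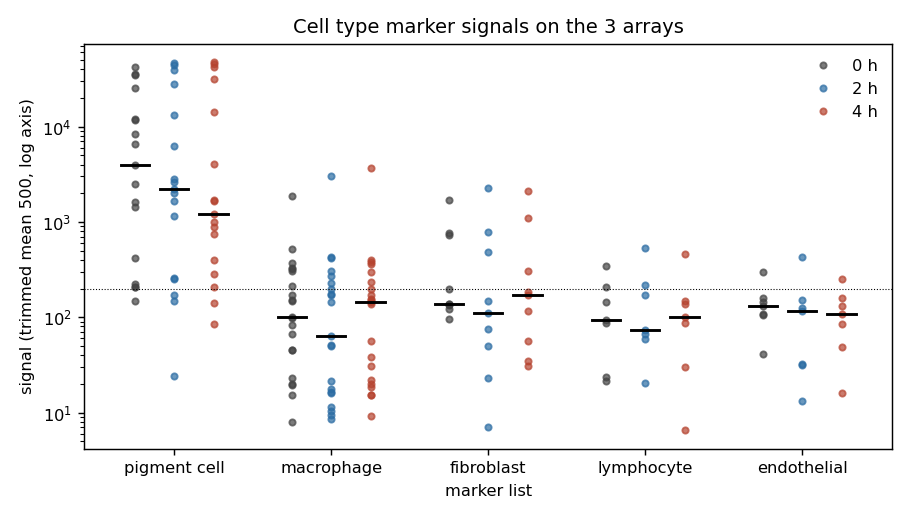
Signal of cell type marker genes on each array (log scale, arbitrary units after scaling to a 2% trimmed mean of 500), 1 point per gene and a line at each list's median. The dotted line marks a signal of 200. The median of the 17 pigment cell markers was 3976 at 0 h, against 100.1 for the 21 macrophage markers.

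The comparison of 2 h with 0 h asked which transcripts differed early in treatment. Ccn1, Dusp6 and Myc were among the genes furthest below their 0 h signal at 2 h. Ccn1, a matricellular protein gene of the immediate early class, had a signal of 5477 at 0 h and 212 at 2 h, 25.9-fold lower (log2 ratio -4.69 ± 0.12, SD over 2 probe sets). Dusp6, a phosphatase that acts on ERK, was 17.2-fold lower at 2 h, and the transcription factor Myc was 14.8-fold lower. Among the 9723 genes, 553 were at least 2-fold lower and 137 at least 2-fold higher at 2 h. Differences of 4-fold or more were found in 70 lower and 10 higher genes.

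Phlda1 had a log2 ratio of -3.67, and Id3, an inhibitor of basic helix-loop-helix transcription factors, of -3.35 at 2 h. Rgs16, a regulator of G protein signalling, stood at -3.25 ± 0.20 (SD over 3 probe sets). The polo-like kinase Plk2 was at -3.23, the planar cell polarity gene Prickle1 at -3.0, and the immediate early response genes Ier3 and Ier2 at -3.0 and -2.91. Slc38a2, a transporter of neutral amino acids, was at -2.92 ± 0.75 (SD over 2 probe sets), and Rusc2 at -2.85. Lower bounds were obtained for genes under the signal floor at 2 h. Sox21, a transcription factor of the SOX family, was at least 14.2-fold lower, Klf6, a Krüppel-like factor, at least 8.61-fold lower, and Setd1b, a histone methyltransferase, at least 5.75-fold lower. The genes highest at 2 h each rested on 1 probe set, and most were dim at 0 h. S100a4, a calcium-binding protein, had a signal of 369 at 0 h and 1637 at 2 h, 4.43-fold higher. The zinc finger gene Zfp385a was 4.69-fold higher from a signal of 153. Atp4b, a subunit of the gastric proton pump, was 4.10-fold higher, and Arhgap27 was also 4.10-fold higher, from signals of 106 and 107. Next came Lrrc23 (log2 ratio 1.93), Lhpp (1.93), Vill (1.75), Sgsm3 (1.75), Cdc42bpg (1.70), the hexokinase Hk3 (1.70), Pdlim1 (1.68) and Perm1 (1.65). Pgm3, an enzyme of UDP-N-acetylglucosamine synthesis, was at least 5.01-fold higher, Clic6 at least 4.94-fold higher and Slc25a53 at least 4.11-fold higher.

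Simulated unchanged arrays with the probe-level spread gave a mean of 145 genes at least 2-fold lower and 145 at least 2-fold higher at 2 h. The 553 lower genes exceeded this number and the 137 higher genes did not. Higher genes did exceed their simulated numbers with equal medians (229 against 144) and with quantile normalization (233 against 150). The simulation is centred on 0, whereas the median log2 ratio of all genes was 0.14 and 0.03 in these scalings. A shift of the whole array may therefore add to these 2 counts. Of the lower genes with at least 2 passing probe sets, 133 of 152 had the same sign in all of them, against 22 of 32 higher genes, and all were at least 2-fold different in 60 and 5. These tallies include the probe set that stood for the gene. The split depended on how arrays were scaled. Lower genes made up 80.1% of those at least 2-fold different in the main setting, 61.6% (368 lower, 229 higher) with equal medians, 63.2% (401 lower, 233 higher) with quantile normalization and 92.8% (917 lower, 71 higher) with scaling to the hybridization spike-ins.

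At 4 h, Ccn1, Dusp6 and Id3 were again among the genes furthest below 0 h, beside Id2 and Rhob. Ccn1 was 46.6-fold lower (log2 ratio -5.54 ± 0.33, SD over 2 probe sets) with a signal of 117, and Dusp6 was 40.8-fold lower. Id3 was 35.3-fold lower, and its relative Id2 25.3-fold lower (-4.66 ± 0.29, SD over 2 probe sets). Rhob, a small GTPase, had a signal of 11973 at 0 h and 426 at 4 h, 28.1-fold lower. In total 1396 genes were at least 2-fold lower and 226 at least 2-fold higher, and 301 were at least 4-fold lower against 14 at least 4-fold higher.

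Ier3 was 22.4-fold lower at 4 h, the transcription factor Cebpb 19.6-fold lower (-4.29 ± 1.70, SD over 2 probe sets) and Slc38a2 18.5-fold lower (-4.21 ± 1.4, SD over 2 probe sets). Bhlhe40, a circadian repressor, was 17.8-fold lower, Ccn2, also known as connective tissue growth factor, 17.8-fold lower, and Prickle1 17.4-fold lower. Nup62, a protein of the nuclear pore, stood at -4.05 ± 0.68 (SD over 4 probe sets). Bounds for genes under the floor at 4 h were at least 16.5-fold lower for Tob1, an antiproliferative regulator, at least 15.5-fold for the tyrosine kinase Abl1 and at least 13.9-fold for cyclin F (Ccnf). Among genes higher at 4 h, S100a4 was 4.93-fold, Atp4b 4.98-fold, Lhpp 4.2-fold, Arhgap27 3.86-fold and Zfp385a 3.60-fold higher. Sh3bgrl was the 1 gene of the 12 highest with several probe sets, with signals of 793, 1332 and 3207 and a log2 ratio of 2.02 ± 0.45 (SD over 3 probe sets). The others were the zinc finger genes Zfp938 (log2 ratio 1.90) and Zscan5b (1.87), the kinase Cdkl2 (1.83), Sh3gl3 (1.78), the transporter Slc41a3 (1.77) and AY036118 (1.75). Pgm3 was at least 5.84-fold higher, Wdtc1 at least 5.83-fold and Neto1 at least 5.37-fold.

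Simulated unchanged arrays gave 241 lower and 238 higher genes at 4 h, so the 1396 lower genes exceeded that number and the 226 higher genes did not. With equal medians the higher genes did exceed it (724 against 242), as they did with quantile normalization (431 against 258). In these scalings the median log2 ratio of all genes was 0.24 and 0.05, against a simulation centred on 0. A shift of the whole array may therefore add to the higher genes there. All passing probe sets had the same sign in 427 of 480 lower genes and in 54 of 70 higher genes, and all were at least 2-fold different in 226 and 15. The share of lower genes among those at least 2-fold different was 86.1%, against 54.6% (872 lower, 724 higher) with equal medians, 69.7% (991 lower, 431 higher) with quantile normalization and 97.1% (2206 lower, 65 higher) with spike-in scaling. The median log2 ratio of all genes was -0.01 at 2 h and -0.07 at 4 h, and it moved by 0.15 and 0.31 with equal medians, by 0.04 and 0.12 with quantile normalization and by -0.22 and -0.32 with spike-in scaling. Values of gene lists are therefore given relative to the median of all genes. That median is not matched for signal, and lists of bright genes tended to lie above it in this scaling. Random lists matched in expression to the ribosomal protein genes had median log2 ratios mostly from 0.17 to 0.54 at 4 h. A positive relative median is therefore not by itself a rise, whereas the percentile of a list compares genes of like signal. From the hybridization times in the file headers, the 4 h array was taken to be from a later fluidics run on the same day than the other arrays. Run and time cannot be told apart for it. The modules also differed, with 3, 4 and 1 for the arrays at 0, 2 and 4 h.

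**Figure D2:**
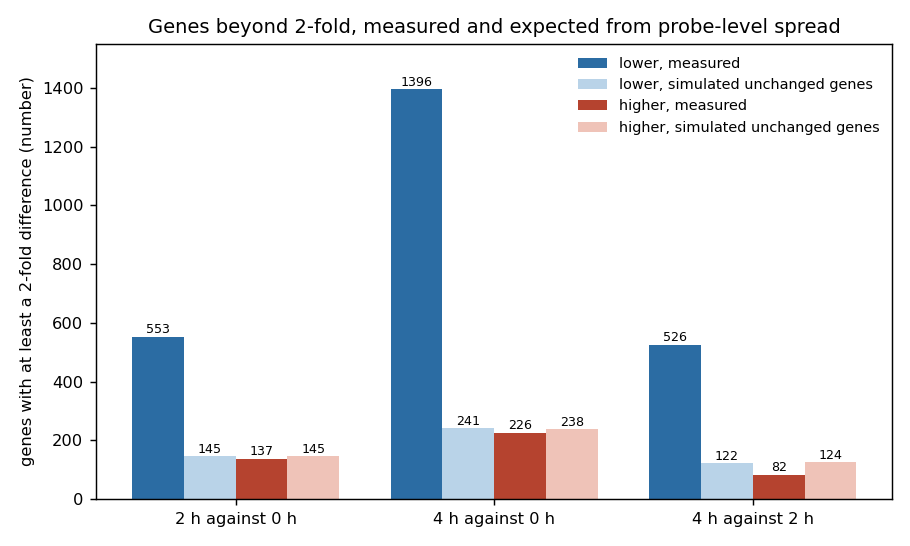
Number of genes at least 2-fold higher or lower in each comparison (bars, from 0), beside the mean of 100 simulations of unchanged arrays with the probe-level spread. The 553 and 1396 lower genes at 2 h and 4 h stand above the simulated 145 and 241, and the 137 and 226 higher genes do not in this scaling.

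Gene lists fixed before the data were examined were read as percentiles of their median among 10000 random lists of like expression, which describes these 3 arrays only. Counts of lower members are to be read against all 9723 genes, of which 5.69% were at least 2-fold lower at 2 h and 14.4% at 4 h. The immediate early genes stood lowest. Of 16 members that passed the filter, 12 were at least 2-fold lower at 2 h and 13 at 4 h, and none was 2-fold higher at either time. Their relative median was -1.84 at 2 h and -1.74 at 4 h, below all random lists at both times. Their median signal was 863, 219 and 198. Members near the signal floor at 2 h could hardly fall further by 4 h. Ccn1 and Ier3 were the lowest members at 4 h. Members chosen after their values were seen included Fos (-1.33 at 2 h and -1.70 at 4 h) and Jun (-2.17 ± 0.75 and -1.92 ± 1.24, SD over 2 probe sets), which encode subunits of AP-1. Maff, a small Maf transcription factor, was the highest member, at 0.56 and 0.97, followed by Fosb at -0.25 and -0.09.

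The list of unfolded protein and integrated stress response genes came next. Of 14 members, 7 were at least 2-fold lower at 2 h and 10 at 4 h, with relative medians of -0.97 and -1.34, again below all random lists. Herpud1, a membrane protein of endoplasmic reticulum-associated degradation, was at -1.82 ± 0.28 and -2.99 ± 0.82 (SD over 2 probe sets), and Ddit4, an inhibitor of mTORC1 signalling, at -1.61 and -2.64. Named after their values were seen, the transcription factors Atf4 and Xbp1 were at -1.29 ± 0.18 and -2.54 ± 0.42 (SD over 2 probe sets) and at -1.16 ± 0.75 and -2.21 ± 0.61 (SD over 4 probe sets). For Xbp1 the 2 h value was 0.23 when probe sets with cross-hybridisation suffixes were left out. Psat1, an enzyme of serine synthesis, was at 0.50 ± 0.32 and 0.74 ± 0.28 (SD over 2 probe sets), and the chaperone cofactor Sdf2l1 at 0.47 and 0.67. Hspa5, the chaperone BiP, was named after its values were seen and stood at 0.03 ± 0.18 and 0.01 ± 0.50 (SD over 3 probe sets).

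Of 20 p53 target genes that passed the filter, 3 were at least 2-fold lower at 2 h and 9 at 4 h, and none was 2-fold higher at either time. This list had a relative median of -0.33 at 2 h (percentile 0.75) and -0.31 at 4 h (percentile 7.30). Without the expression filter the 2 h percentile was 10.0, and with suffixed probe sets left out the 4 h percentile was 0.32. Ccng1, cyclin G1, had the highest ratios, at 0.41 ± 0.18 and 0.84 ± 0.08 (SD over 3 probe sets), followed by the receptor Epha2 at 0.39 and 0.68. Plk2 was at least 12.4-fold lower at 4 h, and Ppm1d, a phosphatase that dampens the DNA damage response, was at -1.13 ± 0.18 (SD over 2 probe sets) at 2 h and at least 4.53-fold lower at 4 h. Chosen after their values were seen, Cdkn1a, the cell cycle inhibitor p21, was at 0.05 ± 0.23 and 0.22 ± 0.02 (SD over 2 probe sets), while Mdm2, the ubiquitin ligase of p53, was at -1.60 ± 0.05 and -2.14 ± 0.06 (SD over 2 probe sets).

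The pigment cell marker list did not stand apart at either time in the main setting, but did in some alternatives given below. Sox10, a transcription factor of the melanocyte lineage, had signals of 11710, 2640 and 892, with log2 ratios of -2.15 ± 0.19 and -3.71 ± 0.82 (SD over 3 probe sets). Mitf, the main regulator of pigment genes, had signals of 6576, 2031 and 739 and ratios of -1.70 ± 0.25 and -3.15 ± 0.69 (SD over 2 probe sets). Mc1r, the melanocortin receptor, and Rab38, a GTPase of melanosome transport, were the other members at least 2-fold lower at 4 h (chosen after their values were seen), at -1.73 ± 0.05 and -1.06 ± 0.02 (SD over 2 probe sets each). Tyrp1 stood at 0.05 ± 0.05 and 0.15 ± 0.11 (SD over 3 probe sets), Dct at 0.17 and 0.26, Pmel at 0.38 and 0.36, and the endothelin receptor Ednrb at 0.29 and 0.45. Over the 14 passing markers, 2 were at least 2-fold lower at 2 h and 4 at 4 h. The relative median was 0.11 (percentile 20.3) and 0.097 (percentile 7.10), while the mean log2 ratio was -0.34 and -0.65. With quantile normalization the relative median was -0.20 (percentile 1.61) and -0.18 (percentile 10.5). It was -0.38 at 2 h without the filter (percentile 0.01), and with a filter of 400 it was -0.23 at 4 h (percentile 0.07).

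**Figure D3:**
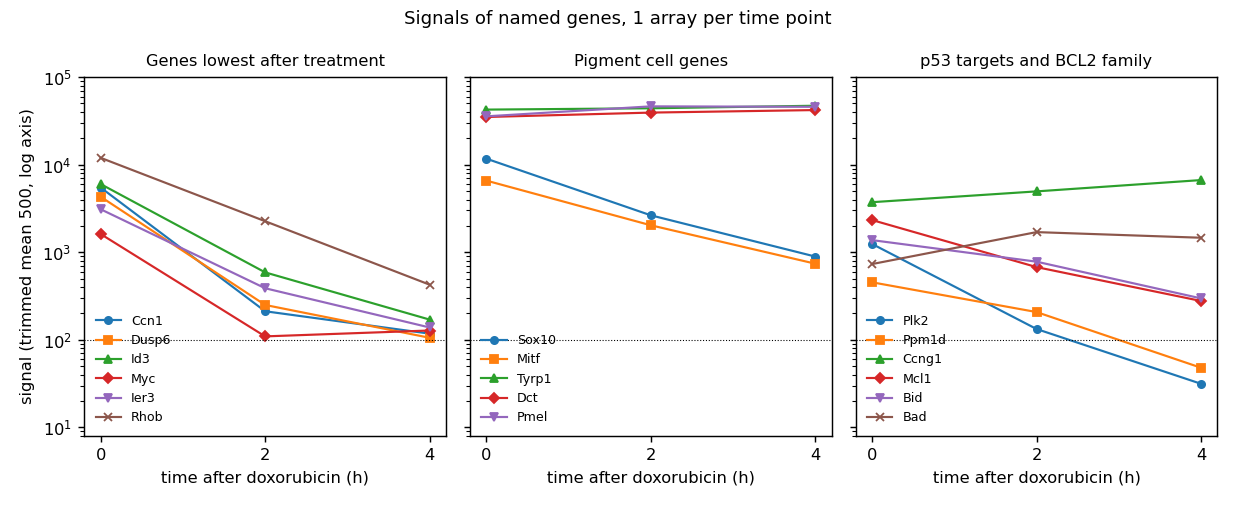
Signal of single genes at 0, 2 and 4 h (log scale, arbitrary units after scaling), 1 line per gene and 1 array per time point. The dotted line marks the floor of 100. Ccn1 went from 5477 to 212 and 117 and Sox10 from 11710 to 2640 and 892, while Tyrp1 stayed between 42568 and 47128.

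Among the cell cycle lists, mitosis genes stood apart low at 2 h, and the DNA replication and histone lists did not stand apart at either time in the main setting. Among 25 DNA replication genes, none differed 2-fold at 2 h and 3 were at least 2-fold lower at 4 h, near the 14.4% of all genes. Cdt1, a licensing factor of replication origins, was at -0.81 ± 0.17 and -3.08 ± 0.21 (SD over 2 probe sets), 8.44-fold lower at 4 h, and Slbp, which binds histone mRNA, at -0.74 and -2.41. The other lower member, chosen after its values were seen, was the licensing factor Cdc6 at -0.63 and -1.32. The helicase subunit Mcm4 was at 0.19 ± 0.07 and 0.61 ± 0.06 (SD over 2 probe sets), and Uhrf1, a factor of DNA methylation maintenance, at 0.33 ± 0.01 and 0.46 ± 0.20 (SD over 2 probe sets). Over all 25 genes the relative median was 0.14 (percentile 45.1) and 0.15 (percentile 15.8), with a mean log2 ratio of -0.23 at 4 h. With quantile normalization it was -0.01 and -0.26 (percentile 0.97 at 4 h). Of 23 mitosis genes, none differed 2-fold at 2 h and 3 were at least 2-fold lower at 4 h, near the 14.4% of all genes. Their relative median was -0.11 (percentile 1.4) and -0.065 (percentile 4.67), and the 2 h percentile was 7.87 with suffixed probe sets left out. The 4 h percentile was 1.27 with quantile normalization, 0.665 with the mean over probe sets and 2.16 with suffixed probe sets left out. The mitotic kinases Plk1 and Ttk were at -0.95 and -2.55 and at -0.12 and -1.70, and cyclin A2 (Ccna2, chosen after its values were seen) at -0.37 ± 0.08 and -1.47 ± 0.29 (SD over 2 probe sets), whereas the kinase Bub1 was at -0.34 and 0.57 and the kinesin Kif23 at 0.30 ± 0.07 and 0.31 ± 0.08 (SD over 2 probe sets). Of 6 histone genes, 1 was at least 2-fold higher at 2 h and none at 4 h, with relative medians of 0.35 (percentile 94.9) and 0.42 (percentile 90.6). With quantile normalization the 2 h percentile was 98.4, and with the mean over probe sets 98.0. The higher member at 2 h was H2bc22, chosen after its values were seen, at 1.27 and 0.27. The linker histone H1f2 was at 0.84 ± 0.26 and 0.88 ± 0.15 (SD over 2 probe sets), H2aw at 0.48 and 0.81, H2bc21 at 0.0033 and -0.10, and H2ax, the histone phosphorylated at DNA breaks, at -0.0020 and -0.71.

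DNA repair and checkpoint genes lay on both sides of the other genes. Of 22 members, none differed 2-fold at 2 h and 3 were at least 2-fold lower at 4 h, near the 14.4% of all genes. Their list had relative medians of -0.14 (percentile 19.1) and 0.0057 (percentile 63.0). Nbn, of the complex that senses double-strand breaks, was at -0.67 and -1.48, the mismatch repair gene Msh6 at -0.43 and -1.30, and the homologous recombination gene Brca1, chosen after its values were seen, at -0.70 ± 0.17 and -1.02 ± 0.34 (SD over 4 probe sets). The checkpoint kinase Atr was at 0.01 and 0.89, and Xrcc5, a subunit of Ku, at 0.55 and 0.86. In the BCL2 family of apoptosis regulators, 1 of 10 genes was at least 2-fold lower and 1 at least 2-fold higher at 2 h, and 3 were lower at 4 h. The family had a relative median of -0.37 (percentile 4.00) and -0.39 (percentile 14.5), and the 2 h percentile was 1.92 with suffixed probe sets left out and 2.20 with the mean over probe sets. Mcl1, a short-lived survival factor, was at -1.79 ± 0.58 and -3.07 ± 0.44 (SD over 6 probe sets), 8.41-fold lower at 4 h. The pro-apoptotic gene Bid was at -0.82 ± 0.13 and -2.21 ± 0.02 (SD over 2 probe sets), and the survival factor Bcl2, chosen after its values were seen, at -0.95 ± 0.22 and -1.60 ± 0.46 (SD over 3 probe sets). Bad, pro-apoptotic as well, was at 1.21 ± 0.63 and 1.00 ± 0.19 (SD over 2 probe sets; just under 2-fold at 4 h), and Bcl2l11 at 0.19 ± 0.39 and 0.23 ± 0.44 (SD over 3 probe sets).

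Among stress and signalling lists, the 11 heat shock genes had 1 member at least 2-fold lower at each time. Their relative median was -0.17 at 2 h (percentile 0.40) and 0.22 at 4 h (percentile 34.0), with a mean log2 ratio of -0.07 at 4 h and a relative median of -0.10 under quantile normalization. The 2 h percentile was 4.35 with suffixed probe sets left out. The co-chaperones Dnajb1 and Bag3 were at -1.12 ± 0.72 and -1.96 ± 1.01 (SD over 2 probe sets) and at -0.62 and -0.82, and the chaperones Hsp90aa1 and Hspa4l at 0.12 ± 0.11 and 0.60 ± 0.04 (SD over 3 probe sets) and at 0.43 ± 0.96 and 0.80 ± 0.82 (SD over 2 probe sets). Of 9 oxidative stress genes, 1 was at least 2-fold lower at each time, with relative medians of 0.15 (percentile 52.1) and 0.24 (percentile 45.9) and mean log2 ratios of -0.03 and -0.02. That member was Osgin1, at -1.73 at 2 h and at least 5.40-fold lower at 4 h. The cystine transporter Slc7a11 was at 0.37 and 0.99, thioredoxin reductase Txnrd1 at 0.38 ± 0.20 and 0.58 ± 0.10 (SD over 3 probe sets) and the glutathione synthesis gene Gclm at -0.06 ± 0.38 and -0.06 ± 0.47 (SD over 2 probe sets). The cAMP-responsive list had 2 of 7 members at least 2-fold lower at both times, the phosphodiesterase Pde4b (-1.76 at 2 h, at least 6.38-fold lower at 4 h) and the nuclear receptor Nr4a3 (-1.51 at 2 h, at least 5.20-fold lower at 4 h). Its relative median was -0.54 (percentile 8.97) and -0.063 (percentile 65.7), with 0.13 at 4 h under quantile normalization. The 2 h percentile was 0.61 without the expression filter and 1.76 with suffixed probe sets left out. Vegfa, an angiogenic growth factor, was at 0.84 and 0.38, and Nr4a2 at -0.18 ± 0.37 and 0.30 ± 0.32 (SD over 2 probe sets).

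Inflammatory lists were short after the filter. NF-kB target genes had 2 of 7 members at least 2-fold lower at each time, the inhibitor Nfkbia (-1.32 ± 0.46 and -1.37 ± 0.77, SD over 5 probe sets) and the transcription factor Irf1 (-1.34 and -1.42). The relative median was -0.10 (percentile 40.4) and -0.28 (percentile 29.1), with 0.039 at 2 h under quantile normalization. The chemokine Cxcl1 was at 0.57 ± 0.39 and 0.51 ± 0.12 and Tnfaip2 at 0.85 ± 0.47 and 0.21 ± 0.29 (SD over 2 probe sets each). None of 5 interferon-stimulated genes differed 2-fold, with relative medians of 0.26 (percentile 93.8) and 0.037 (percentile 76.9). The guanylate-binding gene Gbp2 was at 0.78 ± 0.02 and 0.78 ± 0.45 (SD over 2 probe sets), Ifit3 at 0.45 and 0.25, Ifit2 at -0.57 and -0.95, and Oasl1 at -0.54 and -0.89. None of 8 macrophage markers differed 2-fold, with relative medians of -0.061 (percentile 60.2) and 0.11 (percentile 82.7), and 0.079 at 2 h under quantile normalization. Cd68 was at 0.69 and 0.97, Laptm5 at 0.85 and 0.46, the transcription factor Spi1 at -0.94 and -0.74, and Cd14 at 0.32 and -0.51. Of 3 fibroblast markers, Col1a2 was at -0.61 and -1.27, Col1a1 at 0.41 ± 0.09 and 0.31 ± 0.54 (SD over 2 probe sets), and Postn at 0.04 and 0.51. The relative median of these 3 genes was 0.052 (percentile 58.3) and 0.38 (percentile 85.3), and the mean log2 ratio was -0.06 and -0.15. The lymphocyte and endothelial lists kept 1 gene each, Cd8a at 0.64 and 0.43 and Kdr at 0.53 and -0.23.

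Of the metabolic and ribosomal lists, ribosome biogenesis stood apart low at 4 h, and the others did not stand apart at either time in the main setting. Of 10 hypoxia and glycolysis genes, 1 was at least 2-fold lower at 4 h, the hexokinase Hk2 at -0.73 and -1.58. Egln3, an oxygen sensor, was at -0.35 ± 0.20 and -0.44 ± 0.11 (SD over 2 probe sets), P4ha1 at 0.28 ± 0.15 and 0.55 ± 0.26 (SD over 2 probe sets) and Bnip3 at 0.38 and 0.49. The relative median was 0.19 (percentile 73.6) and 0.27 (percentile 66.9), with -0.015 and -0.090 under quantile normalization. Among 12 cholesterol synthesis genes, none differed 2-fold at 2 h, and 3 were at least 2-fold lower and 1 at least 2-fold higher at 4 h. Squalene epoxidase, Sqle, was at -0.49 and -2.43, Msmo1 at -0.21 and -1.11 and Hmgcs1 (chosen after its values were seen) at -0.50 ± 0.20 and -1.02 ± 0.31 (SD over 4 probe sets), while Idi1 was at 0.34 ± 0.19 and 1.04 ± 0.35 (SD over 2 probe sets) and Fdps at 0.66 and 0.81. As a list they had a relative median of -0.036 (percentile 40.6) and 0.044 (percentile 59.6), with mean log2 ratios of -0.08 and -0.22 and a relative median of 0.041 at 2 h under quantile normalization. Of 20 ribosome biogenesis genes, 3 were at least 2-fold lower at 4 h, near the 14.4% of all genes. Rrs1 was at -0.36 ± 0.12 and -1.67 ± 0.07 and Wdr43 at -0.62 ± 0.07 and -1.55 ± 0.38 (SD over 2 probe sets each), Nob1 (chosen after its values were seen) at -0.49 and -1.03, and the nucleolar proteins Ncl and Dkc1 at 0.02 ± 0.17 and 0.64 ± 0.15 (SD over 5 probe sets) and at 0.43 ± 0.28 and 0.42 ± 0.20 (SD over 3 probe sets). The relative median was 0.014 (percentile 5.54, with -0.12 under quantile normalization) and -0.044 (percentile 1.82). The 4 h percentile was 5.02 with quantile normalization and 2.56 with the mean over probe sets, which gave 2.41 at 2 h. None of 11 ribosomal protein genes differed 2-fold, with relative medians of 0.26 (percentile 44.0) and 0.35 (percentile 22.7), and -0.019 and -0.048 under quantile normalization. Rps19 was at 0.78 and 0.88, Rps6 at 0.55 and 0.84, Rps2 at 0.17 and 0.04, and Rpl8 at 0.0013 and 0.05.

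**Figure D4:**
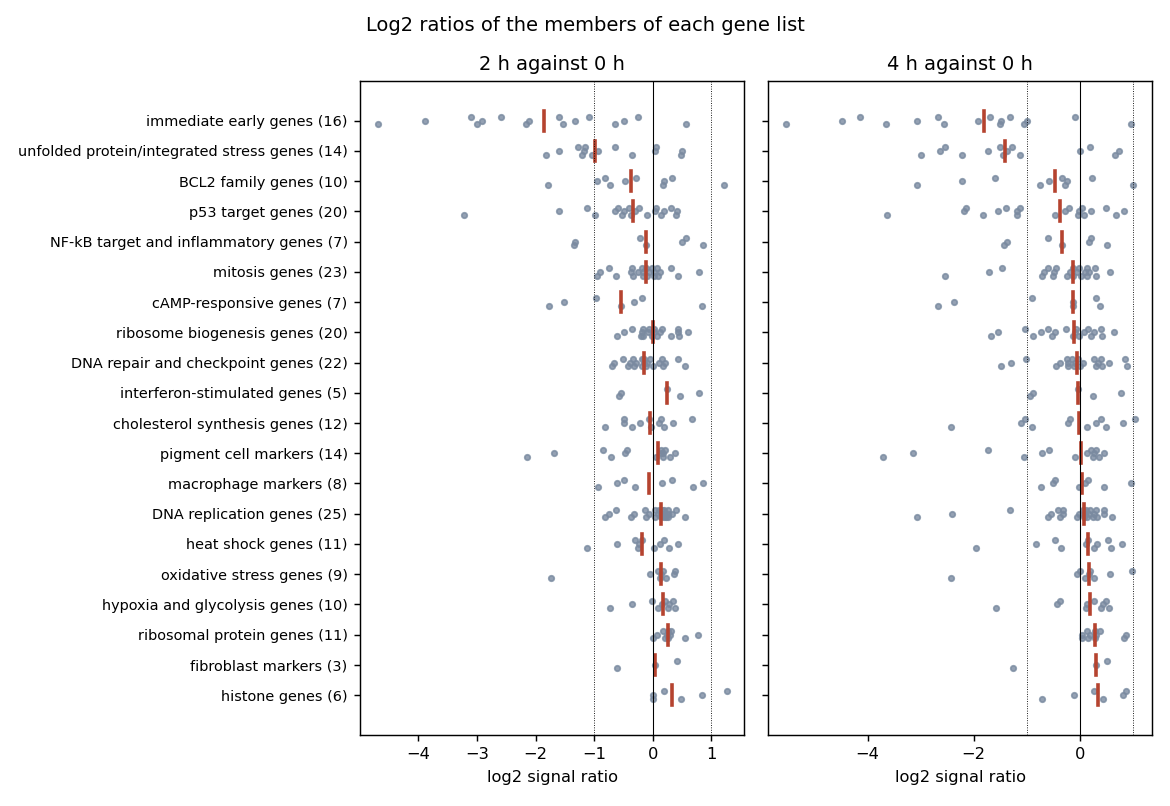
Log2 signal ratio of each passing list member at 2 h and 4 h against 0 h, 1 point per gene, with a red bar at the list's median and the number of members in brackets. Dotted lines mark 2-fold. The medians, here not relative to all genes, were -1.86 and -1.81 for the immediate early genes and -0.98 and -1.41 for the stress response genes.

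Between 2 h and 4 h, different lists moved apart. The stress response list lay lower at 4 h than at 2 h, with a relative median of -0.43 (percentile 0.02) and 4 of 14 members at least 2-fold lower. These were Atf4 (-1.26 ± 0.24, SD over 2 probe sets), Herpud1 (-1.17 ± 0.53, SD over 2 probe sets), Xbp1 (-1.05 ± 0.31, SD over 4 probe sets) and Ddit4 (-1.03). The ribosome biogenesis list did so as well, at -0.28 (percentile 0.01) with 1 of 20 members at least 2-fold lower, Rrs1 (-1.30 ± 0.20, SD over 2 probe sets). The immediate early list had a relative median of 0.10 (percentile 89.8) in this comparison. Of its 16 members, 2 were at least 2-fold lower, Ccn2 (-1.55) and Ier3 (-1.49). Its median signal at 2 h was 219, against 1063 for the stress response list. Members such as Myc (109 at 2 h) and Klf6 (88.9, under the floor) could hardly fall further. The contrast between the immediate early and stress response lists may therefore come in part from the floor. Heat shock genes lay higher at 4 h than at 2 h, at 0.32 (percentile 99.3, but 93.4 without the filter and 89.2 with a filter of 400), and DNA repair genes at 0.20 (percentile 98.7, but 93.0 with quantile normalization and 97.4 with a filter of 400). The p53 target list stood at -0.27 (percentile 1.71), and this call was lost in 6 alternatives. The percentile was 3.25 with spike-in scaling, 3.91 with the mean over probe sets, 4.84 with quantile normalization, 9.81 with a filter of 400 and 66.1 without the filter, and the sign reversed with a floor of 200 (0.026). Across all genes with equal medians, 175 higher genes stood against 135 simulated, but there the median log2 ratio was 0.09 and not 0. In the main setting, 526 were at least 2-fold lower and 82 at least 2-fold higher at 4 h than at 2 h, against 122 and 124 in simulated unchanged arrays. Lower genes were 86.5% of these, against 67.2% (359 lower, 175 higher) with equal medians, 72.8% (377 lower, 141 higher) with quantile normalization and 92.6% (704 lower, 56 higher) with spike-in scaling.

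Most genes that were lower at 2 h were also lower at 4 h. Of the 553 genes at least 2-fold lower at 2 h, 427 (77.2%) were also at least 2-fold lower at 4 h, among them Ccn1, Dusp6, Id3, Sox10 and Mitf, and 969 genes were so at 4 h only. Independent lists of these sizes would share 79.4 genes, and simulated unchanged arrays with a shared 0 h array had 68.2 in common. Of the 137 genes higher at 2 h, 85 were also higher at 4 h, among them S100a4 and Atp4b, against 3.18 for independent lists. The simulation gave a mean of 66.5 and a maximum of 86, so this overlap did not exceed every simulated one. The overlap of lower genes did (maximum 92). However, the simulated lower lists held a mean of 145 and 241 genes, against 553 and 1396 measured, and larger lists share more genes. Part of either overlap may come from the shared 0 h array. No gene was at least 2-fold lower at one time and at least 2-fold higher at the other. Of the 553 genes, 358 (64.7%) had a lower signal at 4 h than at 2 h. The median log2 ratio of all 9723 genes in this comparison was -0.06, so most other genes were lower at 4 h too. That median was 0.09 with equal medians, so such a share depends on the scaling.

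Long genes can respond differently to a topoisomerase poison, so log2 ratios were compared with genomic gene length. Across 9712 genes, which are not independent replicates, Spearman's rank correlation was -0.150 at 2 h, -0.0888 at 4 h and 0.0219 for 4 h against 2 h. In 4 bins of length holding like numbers of genes, with medians of 5.20, 15.7, 33.9 and 96.8 kb, the median log2 ratio was 0.10, 0.02, -0.04 and -0.14 at 2 h and 0.04, -0.06, -0.06 and -0.18 at 4 h. With quantile normalization the correlation was -0.102 at 2 h and -0.0401 at 4 h.

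Control probe sets described the quality of the RNA and of the hybridisation. The ratio of 3' to 5' signal was 1.07, 1.10 and 1.18 for Actb at 0, 2 and 4 h, 0.826, 0.824 and 0.803 for Gapdh, and 3.53, 4.64 and 2.81 for the transferrin receptor Tfrc. The 3 probe sets for 18S ribosomal RNA had a geometric mean signal of 310 at 0 h, 612 at 2 h and 826 at 4 h. The 18 hybridization spike-in probe sets were higher by a mean log2 ratio of 0.22 ± 0.11 at 2 h and 0.32 ± 0.17 at 4 h (SD over probe sets).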

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

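The test of the Tfrc control, the test of the lists over all settings, the tests of the fluidics run, the test against the simulated spread and the test of the lower members' other probe sets were chosen only after the result was seen. So was scaling to the hybridization spike-ins. The patterns and tests below rest on 1 array per time point.

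More genes were at least 2-fold lower than higher at 4 h. Scaling alone is argued against as the whole cause. The ratio of genes 4-fold below to genes 4-fold above the median of all genes was at least 9.46 in each of 4 scalings. Setting that median to 0 all but cancels 1 factor per array. Only quantile normalization, which gave the 9.46, therefore adds a separate check. The number of genes past 2-fold moved with the scaling. The later fluidics run of the 4 h array, inferred from times in the file headers, is argued against as the whole cause. At 2 h, in 1 run with 0 h, the same ratio of genes 4-fold below to above was at least 4.73, again with quantile normalization. The share of the run in the further difference at 4 h cannot be told apart from time. RNA degradation stays open, because the log2 difference of the Tfrc 3' to 5' ratio was -0.33 but this is 1 transcript, and Actb and Gapdh lie near the top of the signal range. Gene length stays open as a contributor, with a rank correlation of -0.0888 across genes that lies between the bounds set for either outcome. The pattern was not confined to long genes. From the shortest to the longest of 4 bins of length, 13.8%, 14.0%, 12.9% and 16.8% of genes were at least 2-fold lower at 4 h. In the same bins, 3.29%, 2.02%, 1.73% and 2.27% were at least 2-fold higher.

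The immediate early and stress response lists were low at 4 h. Quantile scaling, the floor or the filter is argued against, since the higher of their percentiles over all settings was 0, while scalings by 1 factor per array can hardly move it and test nothing. Noise of single probe sets is argued against by the 76.7% of 30 members that were at least 2-fold lower, against 2.86% of simulated unchanged genes. Of the 9 members with several probe sets, 66.7% had all of them lower. This share lies between the bounds set for either outcome and decides nothing. A later test took the 6 members at least 2-fold lower in their first probe set. The mean over their other probe sets had a median log2 ratio of -3.27 (-5.08 to -1.69), which argues against noise for these 6 members only. The later fluidics run is argued against as the whole cause, since at 2 h, in 1 run with 0 h, 63.3% of the members were already at least 2-fold lower, against 1.84% simulated, and the drug was not separated from medium change or handling over time.

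Genes at least 2-fold lower at 2 h tended to be lower still at 4 h. A chance low signal on the 2 h array would let another probe set of the same gene go back up at 4 h. In the second probe set of 152 genes chosen by their first, the median log2 ratio of 4 h against 2 h was -0.37 (bootstrap range -0.62 to -0.24), against -0.04 for all genes, which argues against that explanation. The later fluidics run of the 4 h array stays open, as does an effect of treatment, which was not tested.

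Several lists had relative medians of opposite sign at 2 h and 4 h against 0 h in the main setting, and the difference between times was not tested. The relative medians were -0.14 and 0.0057 for DNA repair and checkpoint genes, -0.17 and 0.22 for heat shock genes, -0.036 and 0.044 for cholesterol synthesis genes, 0.014 and -0.044 for ribosome biogenesis genes, and -0.061 and 0.11 for macrophage markers. With quantile normalization only DNA repair and checkpoint genes kept opposite signs (-0.058 and 0.12). Heat shock and ribosome biogenesis genes were then negative at both times, and cholesterol synthesis genes and macrophage markers positive. Among matched random lists, heat shock genes (percentiles 0.40 and 34.0) and ribosome biogenesis genes (5.54 and 1.82) lay below the middle at both times. Macrophage markers (60.2 and 82.7) lay above it at both. Among named genes at least 2-fold lower at 2 h, Sox21 had the opposite sign at 4 h, with -3.83 (a bound, from 1 probe set) and 0.18 and signals of 1418, 89.9 and 1611, and this difference was not tested either.

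Signals outside the gene comparisons differed too. The 18S ribosomal RNA probe sets had mean log2 ratios of 0.98 at 2 h and 1.42 at 4 h, and 0.77 and 1.09 with spike-in scaling. These were 1.14 and 1.72 with equal medians and 1.15 and 1.68 with quantile normalization. The hybridization spike-ins stood at 0.22 and 0.32, above 0 in 18 of 18 probe sets at both times. They stood at 0.11 and 0.18 with quantile normalization and at 0.37 and 0.63 with equal medians. Of 1851 passing probe sets without a single gene name, 103 were at least 2-fold lower at 2 h and 153 at 4 h, against 48 and 72 at least 2-fold higher.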

How the results depend on the processing

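Spike-in scaling was added after the data were seen. No paired analysis was possible because each time point has 1 array, which leaves no spread to estimate. Exonic length was not run, since the gene table used gives genomic span only. The values as deposited moved nothing, because 1 factor serves every array, which says nothing about stability. Genes higher at 2 h and at 4 h had median signals at 0 h of 164 and 262, against 774 and 823 for the lower genes. Choosing genes by their ratio to 0 h favours this difference. Whether dim signals limit the higher genes was not tested by it. Where a value moved, the cause was not tested beyond the setting itself.

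Counts of genes that moved by over 1.5 times are given as 2 h, 4 h and 4 h against 2 h. Higher genes numbered 229, 724 and 175 with equal medians, 233, 431 and 141 with quantile normalization, 343, 405 and 254 without a filter, and 34, 116 and 23 with a filter of 400. They were 71 and 65 at 2 h and 4 h with spike-in scaling, 79 at 2 h and 45 for 4 h against 2 h with a floor of 200, and 52 for 4 h against 2 h with an offset of 50. Lower genes numbered 368 and 872 with equal medians, 917 and 2206 with spike-in scaling, 1027 at 2 h without a filter, 239, 780 and 253 with a filter of 400, and 327 for 4 h against 2 h with a floor of 200. Genes higher at both times were 170, 162, 37, 34, 53, 136 and 15 with equal medians, quantile normalization, spike-in scaling, a floor of 200, an offset of 50, no filter and a filter of 400. Genes lower at both times were 274 with equal medians, 740 with spike-in scaling, 735 without a filter and 204 with a filter of 400. In every setting lower genes outnumbered higher genes in all 3 comparisons. Lower genes exceeded every simulation of unchanged arrays in all 4 scalings. Higher genes did so with equal medians in all 3 comparisons and with quantile normalization at 2 h and 4 h. The simulations are centred on 0, so a shift of the whole array can add to such an excess. At 4 h the median log2 ratio of all genes was 0.24 with equal medians and -0.39 with spike-in scaling.

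Of 60 list medians, 13 stood apart, where 3 of 100 lists of unchanged genes did so in simulated data. The 60 medians are not independent, since the 3 comparisons share arrays, and some of the 13 may stand apart by chance. The alternatives of the 13 medians include the values as deposited, equal medians and spike-in scaling. These use 1 factor per array and can hardly move a percentile. The immediate early list at 2 h and 4 h and the stress response list in all 3 comparisons stood apart in every alternative. In all, 128 of the 143 alternative values of the 13 medians still stood apart with the same sign. Those that ceased to were p53 targets at 2 h without a filter (-0.11) and for 4 h against 2 h with quantile normalization (-0.18), spike-in scaling (-0.23), no filter (0), a filter of 400 (-0.15) and the mean over probe sets (-0.21), with the sign reversed at a floor of 200 (0.026). Mitosis (-0.070) and heat shock genes (-0.079) did so at 2 h without suffixed probe sets, ribosome biogenesis at 4 h with quantile normalization (-0.21) and the mean over probe sets (-0.019), and for 4 h against 2 h DNA repair with quantile normalization (0.15) and a filter of 400 (0.18) and heat shock without a filter (0.15) and with a filter of 400 (0.19). Medians that came to stand apart were, at 2 h, histones with quantile normalization (0.39) and the mean over probe sets (0.41), the BCL2 family with the mean (-0.40) and without suffixed probe sets (-0.44), cAMP-responsive genes without a filter (-0.63) and without suffixed probe sets (-0.93), ribosome biogenesis with the mean (-0.020), and pigment markers with quantile normalization (-0.20) and no filter (-0.38). At 4 h these were p53 targets without suffixed probe sets (-0.60), DNA replication with quantile normalization (-0.26), mitosis with quantile normalization (-0.31), the mean (-0.21) and without suffixed probe sets (-0.26), and pigment markers with a filter of 400 (-0.23). For 4 h against 2 h they were mitosis with the mean (-0.12), and the BCL2 family (-0.50) and pigment markers (-0.083) with a filter of 400. At a threshold of 400, macrophage markers with a signal numbered 2, 3 and 1, lymphocyte markers 0 at 0 h and 1 at 2 h, and endothelial markers 0 at 0 h and 0 at 4 h.

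The rank correlation with gene length at 2 h was -0.102 with quantile normalization and -0.0748, -0.0792, -0.105 and -0.221 within 4 bins of expression, from low to high. At 4 h it was -0.0401 with quantile normalization and -0.0525, -0.0331, -0.00683 and -0.0946 within the 4 bins. For 4 h against 2 h it was 0.0564 with quantile normalization and 0.0132, 0.0399, 0.103 and 0.0799 within the 4 bins. Of 6282 alternative values of single genes, 5974 stayed within the probe-level SD and 307 moved by more, while 1 reversed, Xbp1 at 2 h without suffixed probe sets (0.23). The Sf gene family reversed at 4 h in the same setting (0.17). The total of 5974 overstates stability. The values as deposited (598 values), no filter (598) and a filter of 400 (442) keep each gene's probe set and signal, so none could move. Equal medians (596 values, none moved) shift genes nearly alike.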

Other observations

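All families in this part were picked after the data were seen, from 111 groups of at least 10 genes that share a symbol stem. At 4 h against 0 h, 9 families stood apart low among matched random lists and 8 stood apart high, against 2.78 by chance on each side. Zinc finger genes named Zfp were the largest low family. Of 132 members, 50 were at least 2-fold lower and 4 at least 2-fold higher, with a relative median of -0.65 (percentile 0). The Kdm family of histone demethylases had a relative median of -0.86 (percentile 0.47), with 5 of 14 members at least 2-fold lower, among them Kdm6b at -1.70. The Snhg family, non-coding host genes of small nucleolar RNAs, stood at -0.84 (percentile 0.28), led by Snhg5 (-3.01) and Snhg3 (-2.03), which were already at -2.59 and -1.79 at 2 h. On the other side, the Ndufb genes, subunits of mitochondrial complex I, stood at 0.68 (percentile 99.7) with no member beyond 2-fold, and Ndufb2 at 0.87 ± 0.15 (SD over 2 probe sets). The Zfp, Kdm and Ndufb families stood apart in every alternative that was run, with -0.54, -0.74 and 0.21 under quantile normalization. The Snhg family did so in all but a filter of 400, where it was at -0.54 (percentile 2.82).

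Each of the other 13 families ceased to stand apart in at least 1 alternative. The low ones were Klf (-0.84), Klhl (-0.62), Rbm (-0.53), Trim (-0.52), Nup (-0.39) and Sf (-0.022), and the last reversed to 0.17 when suffixed probe sets were left out. The high ones were Ndufa (0.66), Fkbp (0.60), Cd (0.50), Atp (0.47), Aldh (0.38), Ift (0.34) and Cyp (0.28). Some stems, such as Cd, Atp and Sf, gather genes that share letters and not a function.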
